A study of Homo sapiens with 7 samples.

How the data were processed

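Chromatin immunoprecipitation followed by sequencing (ChIP-seq), which counts the DNA fragments that an antibody pulls down from cross-linked chromatin, was carried out in MCF7, an established breast cancer cell line that carries the estrogen receptor (ER) and responds to estrogen. Per the labels' protocols, cells spent 96 h in hormone-free medium (their growth protocol gives 3 days) and then received 20 nM estradiol or the ethanol vehicle for 6 h. The antibodies were against ER, against TRIM24, which the series' design text calls a coactivator, and against H3K4me2, a histone mark. The 7 samples made up 7 groups of 1 sample each. Peak lists of 4 samples were analysed: ER with estradiol, ER with vehicle, TRIM24 with estradiol and TRIM24 with vehicle. The pair of H3K4me2 samples and the input sample were not analysed here. The design text describes 2 antibody amounts and 2 sequencing runs, and whether a list pools them is not given in the sources used here.

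The authors deposited, for each of the 4 samples, peak positions and a score per peak. Peaks were called with MACS without a fragment model, per the file headers. By the convention of that caller the deposited score is -10 times the log10 of the p-value, and a larger score means a firmer call. The lowest score was 50.0 in every list, so each list ends at the authors' calling threshold. In the list of ER with estradiol 13 peaks shared the score 3100 exactly, a value taken here as the caller's cap. Their order in firmness against the peaks scored above 3100 is therefore uncertain. The score is the authors' own value for each peak and was used only to describe, rank or select peaks within a list, with the wider peak first where scores were tied. The MACS version, the aligner, the control library and the read depth of each library are not given in the sources used here. Precision is therefore limited by an unknown depth, and a peak missing from a list can lie just under its threshold.

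A pair of inconsistencies bears on every value. The track lines of both lists labelled TRIM24 contain ER (16E-ER_nomodel and 16N-ER_nomodel), while the sample labels name TRIM24. Those of the ER lists read 17E-ER_nomodel and 17N-ER_nomodel, so between antibodies the lines differ only in the leading number. Whether ER in these lines means the antibody is not given in the sources used here. The groups follow the sample labels throughout. The build is GRCh37 per the submitters' processing notes, but 174 peaks on 3 chromosomes lay past the ends of the GRCh37 chromosomes. No peak on any of the 24 chromosomes lay past the ends of the NCBI36 (hg18) chromosomes. Coordinates are printed as the lists give them, counted from 1, and are read as NCBI36. The chromosome lengths used for that comparison come from general knowledge.

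No genome or annotation of that build was used here, and coordinates were not converted. Nearest genes, the share of peaks at promoters, motif shares and the counts over gene lists, all planned before the data were examined, were therefore not run. Peaks are named by position. The naming rule, also set before the data were examined, takes the 10 peaks with the highest score in each class of a comparison, and the text gives examples from them. A peak at a region named under another class counts under both.

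Peaks of 2 lists were called shared when they overlapped by at least 1 bp. The overlap was computed in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 in place of the planned bedtools, and it was checked against a search over all pairs of peaks. Shares have 95% Wilson intervals and differences between shares have 95% Newcombe intervals. These intervals cover counting error only and treat peaks as independent. Each group held 1 sample, so no difference has a replicate check and no p-value is given. Every overlap was described against 1000 random placements of the same peaks within the stretch that peaks cover on their own chromosome. Random placement can fall in stretches of the genome where no peak can be called, so a second background was added after the data had been examined. It moved each peak by 10 to 100 kb to either side, 1000 times. Shares were also computed by decile and quartile of the score within a list. Classes that differ in score were compared within quartiles of score and of width. For the comparison of TRIM24 with and without estradiol at the same ER peaks, added after the data had been examined, the longer TRIM24 list was also shortened by score to the 7872 peaks of the vehicle list.

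The overlap code was tested on simulated data. With 25% of the ER estradiol peaks planted on TRIM24 estradiol peaks it recovered 24.9% above chance, and with 5% planted on ER vehicle peaks it recovered 4.97%. The Newcombe interval covered a simulated difference in 95.1% of draws. Before the data were examined 7 alternatives were set: an overlap of at least 50% of both peaks, centres within 500 bp, gaps of up to 1 kb, the higher scored 50% of each list, equal list lengths, leaving out chromosomes 1, 17 and 20, which carry copy gains in MCF7, and merging peaks within 500 bp. 1 more, leaving out peaks that overlap all 3 other lists, was added later. Figures were drawn with matplotlib 3.10.9.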

Results

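Binding of ER and of its coactivator TRIM24 was mapped in MCF7 cells with and without estradiol. The 4 lists held 10350 peaks for ER with estradiol, 6392 for ER with vehicle, 14548 for TRIM24 with estradiol and 7872 for TRIM24 with vehicle. Median peak widths were 432, 401, 543 and 517 bp, and the peaks covered 4.95, 2.83, 8.90 and 4.50 Mb. Within the lists, in the same order, median scores were 96.9, 63.1, 70.5 and 67.2, and 51.9, 93.4, 80.1 and 88.9% of peaks scored under 100. These values describe each list and do not compare signal between lists. Each group was 1 sample, so differences have no replicate check, and intervals cover counting error only. Merging all lists gave 32784 sites, of which 27861 (85.0%) were in 1 list only and 136 (0.415%) were in all 4. The track lines of all 4 lists contain ER, those of the lists labelled TRIM24 included. All values for TRIM24 below are values of the lists so labelled.

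Among the autosomes, chromosomes 17, 19 and 20 had the highest peak densities in every list, and chromosome 16 came next except in the ER vehicle list. TRIM24 was more concentrated on these chromosomes than ER. Together chromosomes 16, 17, 19 and 20 held 26.0% (95% interval 25.3 to 26.7) of TRIM24 estradiol peaks and 27.6% (26.6 to 28.6) of TRIM24 vehicle peaks. For ER the shares were 20.2% (19.4 to 20.9) with estradiol and 18.1% (17.1 to 19.03) with vehicle. This set was picked from the densities themselves. Chromosomes 1, 17 and 20, which carry copy gains in MCF7, held 21.4% of TRIM24 and 19.9% of ER estradiol peaks. With vehicle they held 22.8% of TRIM24 and 17.9% of ER peaks. On chromosome 19 TRIM24 estradiol peaks reached 14.5 per Mb, 2.93 times the mean of their list, and ER estradiol peaks reached 6.74 per Mb, 1.91 times theirs. On chromosome 17 the densities were 14.1 and 8.30 per Mb, 2.85 and 2.35 times the means. Chromosomes 4, 13, 18 and X were sparse in every list. On chromosome 18 the density was 0.284 times the mean for TRIM24 with estradiol and 0.511 times for ER with estradiol.

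**Figure D1:**
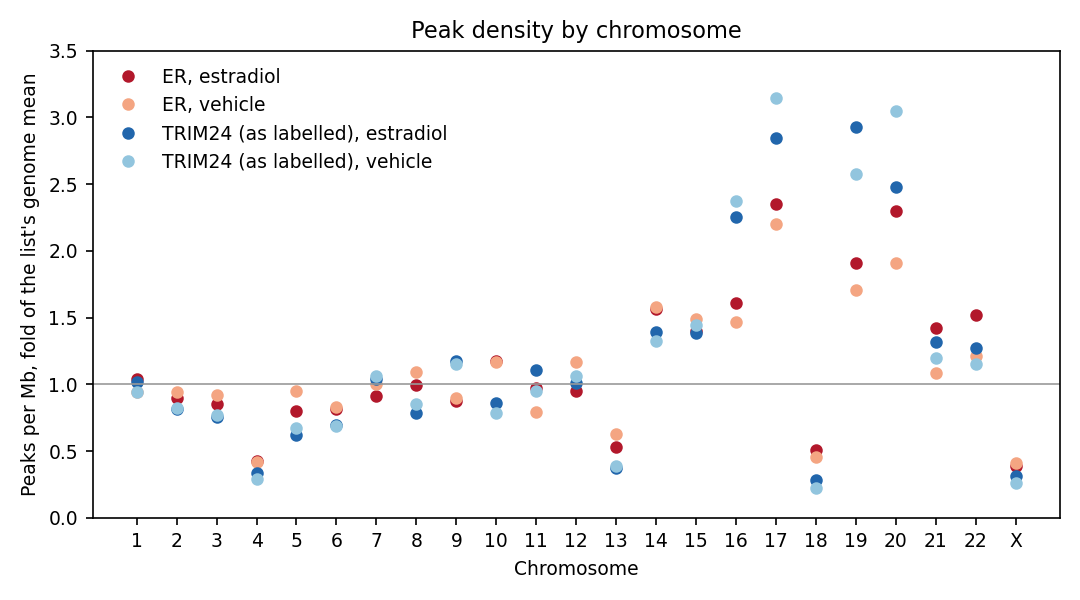
Peak density of the 4 lists on each chromosome (x axis, chromosomes 1 to 22 and X), as peaks per Mb divided by the genome mean of the same list (y axis, line at 1). Each point is 1 list on 1 chromosome, and TRIM24 estradiol peaks (dark blue) stand at 2.93 times their mean on chromosome 19 where ER estradiol peaks (dark red) stand at 1.91 times theirs.

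The first comparison asked which ER peaks were found with estradiol and which without. ER peaks were mostly found under 1 condition only. Of the 10350 ER estradiol peaks, 9759 (94.3%, 93.8 to 94.7) met no ER vehicle peak, and of the 6392 ER vehicle peaks, 5802 (90.8%, 90.0 to 91.5) met no estradiol peak. The strongest ER sites were the exception, since 73 of the 100 highest scored estradiol peaks were also found with vehicle (63.6 to 80.7%). In the lower 9 deciles of score the share was 3.36% (3.01 to 3.75).

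The shared peaks included the highest scored ER peaks of the estradiol list. These lay on chromosome 8 from 102547979 to 102548537 (score 3227), on chromosome 14 from 92553202 to 92554053 (3225) and on chromosome 9 from 137423951 to 137424805 (3156). The region on chromosome 21 from 42669275 to 42670196 and that on chromosome 17 from 46376395 to 46377305 followed at 3100, and both were found with vehicle. Among peaks found only with estradiol the highest scored lay on chromosome 20 from 52173311 to 52174130 (3100). It was followed by a peak on chromosome 9 from 113814091 to 113814778 (2904), which was in no other list, and a peak on chromosome 20 from 48813305 to 48815034 (2800). Of the 10 highest scored estradiol-only peaks, 9 met a TRIM24 estradiol peak and 4 a TRIM24 vehicle peak.

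Peaks found only with vehicle had a median score of 62.7 and a maximum of 312, and vehicle peaks shared with estradiol had a median of 70.3 and a maximum of 2354. The highest scored were 4 wide stretches: 5100 bp on chromosome 18 from 16769401, 8165 bp on chromosome 19 from 32423485, and 2797 and 4907 bp on chromosome 10 from 41702959 and 41712472. The next 6 were 212 to 274 bp wide, and none of the 10 was in another list. The vehicle list itself peaked at a site found with estradiol too, on chromosome 1 from 121185485 to 121187123 (2354), which was in all 4 lists.

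The 591 shared estradiol peaks made up 5.71% (5.28 to 6.17) of the list, 24.01 times the random mean of 0.238% and 12.1 times the mean of 0.472% after local shifts. The highest share among 1000 local shifts was 0.696%. The lists end at a calling threshold and the read depths are unknown, so absence from a list is not absence of binding.

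The second comparison asked the same of TRIM24. By raw share, TRIM24 peaks were shared between conditions more often than ER peaks. Of the 14548 TRIM24 estradiol peaks 2435 (16.7%, 16.1 to 17.4) met a vehicle peak, and of the 7872 vehicle peaks 2459 (31.2%, 30.2 to 32.3) met an estradiol peak. The other 12113 estradiol peaks (83.3%, 82.6 to 83.9) and 5413 vehicle peaks (68.8%, 67.7 to 69.8) were found under 1 condition only. Nearly all of the strongest vehicle peaks persisted, 94 of the top 100 (87.5 to 97.2%), and 76 of the top 100 estradiol peaks were also in the vehicle list (66.8 to 83.3%).

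The highest scored TRIM24 peaks lay on chromosome 20, from 48840305 to 48841221 (score 2701), from 51642225 to 51645090 (2494) and from 26136498 to 26138667 (2358). The 10 highest scored shared TRIM24 peaks were all in the lists of ER with estradiol and ER with vehicle as well. They included 15770 bp on chromosome 17 from 56834979 (1915) and 6797 bp on chromosome 20 from 55271673 (1440). Both of these wide peaks, and the peak from 51642225, lie in stretches, taken up below, where extra copies and dense binding cannot be told apart. Chromosome 20 as a whole is among those said above to carry copy gains in MCF7. TRIM24 peaks found only with estradiol reached a score of 812, on chromosome 20 from 52173418 to 52174037, at the same place as the highest scored estradiol-only ER peak. The next lay on chromosome 2 from 11556033 to 11556570 (753), on chromosome 1 from 7429967 to 7431153 (684) and on chromosome 21 from 42668625 to 42671492 (626). All 10 of the highest scored estradiol-only TRIM24 peaks met an ER estradiol peak, and 7 met an ER vehicle peak. Of the 10 highest scored vehicle-only TRIM24 peaks, 1 met an ER peak, on chromosome 19 from 49913255 to 49914322. The highest scored of them lay on chromosome 18 from 30327076 to 30328188 (253).

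The share of 16.7% was 36.0 times the random mean of 0.464% and 11.4 times the local shift mean of 1.47%. For ER these ratios were 24.01 and 12.1. Relative to local shifts, sharing was thus no higher for TRIM24 than for ER, while relative to random placement it was higher.

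**Figure D2:**
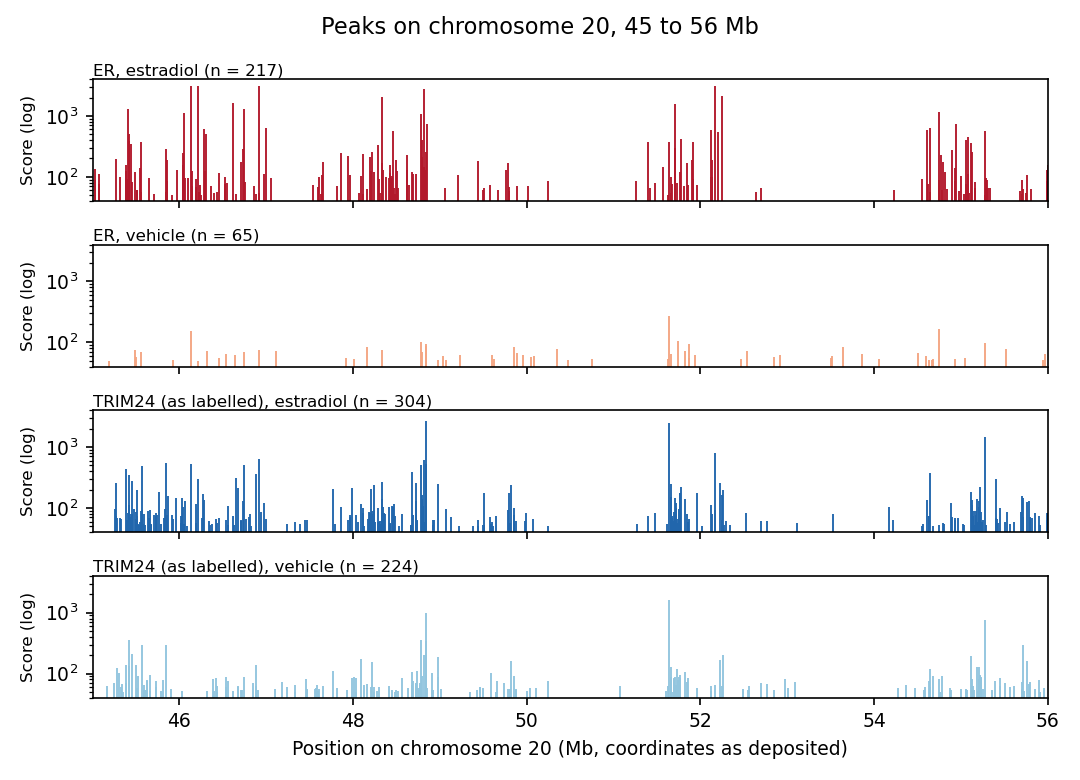
Peaks of the 4 lists on chromosome 20 between 45 and 56 Mb (x axis, position as deposited). Each vertical line is a peak and its height is the authors' score on a log axis; scores are not comparable in size between lists. The stretch held 217 ER estradiol, 65 ER vehicle, 304 TRIM24 estradiol and 224 TRIM24 vehicle peaks.

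The next comparison asked how often ER and TRIM24 peaks coincided. With estradiol they did so at 2494 of the 10350 ER peaks (24.1%, 23.3 to 24.9), and with vehicle at 304 of the 6392 ER peaks (4.76%, 4.26 to 5.31). With estradiol, coincidence was highest among the highest scored ER peaks. It reached 84 of the 100 highest scored ER peaks (75.6 to 89.9%) and 59.3% (56.3 to 62.3) of the top decile, against 20.2% (19.4 to 21.01) of the lower 9 deciles. With vehicle it was 12.5% (10.2 to 15.3) in the top decile and between 2.50 and 5.32%, with no steady rise, in the lower 9. From the TRIM24 side, 85 of the 100 highest scored TRIM24 estradiol peaks (76.7 to 90.7%) and 17.0% of the whole list met an ER estradiol peak.

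The score was 3100 or more at 16 ER estradiol peaks, 13 of them tied at 3100, and 14 of the 16 met a TRIM24 estradiol peak. Of these 14, 13 were also ER vehicle peaks, the exception being the region on chromosome 20 from 52173311. A pair of them, on chromosome 8 from 129223130 to 129224065 and on chromosome 17 from 46376395 to 46377305, met a TRIM24 vehicle peak. Some strong ER sites had no TRIM24 peak. The peaks on chromosome 10 from 95184814 to 95185315 and on chromosome 14 from 76936269 to 76936766 scored 3100 and were in both ER lists and in neither TRIM24 list. Of the 10 highest scored ER estradiol peaks without TRIM24, 9 were found with vehicle. The TRIM24 estradiol peaks that met no ER estradiol peak were led by chromosome 17 from 71292300 to 71293406 (980.3), chromosome 2 from 132745202 to 132750274 (663) and chromosome 17 from 59273212 to 59274427 (634). All 10 of the highest scored of these were in the TRIM24 vehicle list, and 4, among them the region on chromosome 2, met an ER vehicle peak. The ER vehicle peak on chromosome 2, 9860 bp from 132738741, also met an ER estradiol peak, which did not reach the TRIM24 peak.

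Where ER and TRIM24 estradiol peaks overlapped, their centres were a median of 116 bp apart. Within 10 kb, 43.7% of ER estradiol peaks had a TRIM24 estradiol peak, against a mean of 9.49% over 100 random placements. Local shifts were not run for distances, and placement over a whole chromosome takes no account of regional crowding of peaks. The coincidence with estradiol was 34.7 times the random mean of 0.694% and 12.96 times the local shift mean of 1.86%. With vehicle it was 13.8 times the random mean of 0.344% and 6.51 times the local shift mean of 0.730%. The vehicle share ranged from 2.68% (overlap of at least 50% of both peaks) to 7.17% (gaps of up to 1 kb). It was 2.98% without sites common to all lists, a step that removes coinciding peaks by construction.

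**Figure D3:**
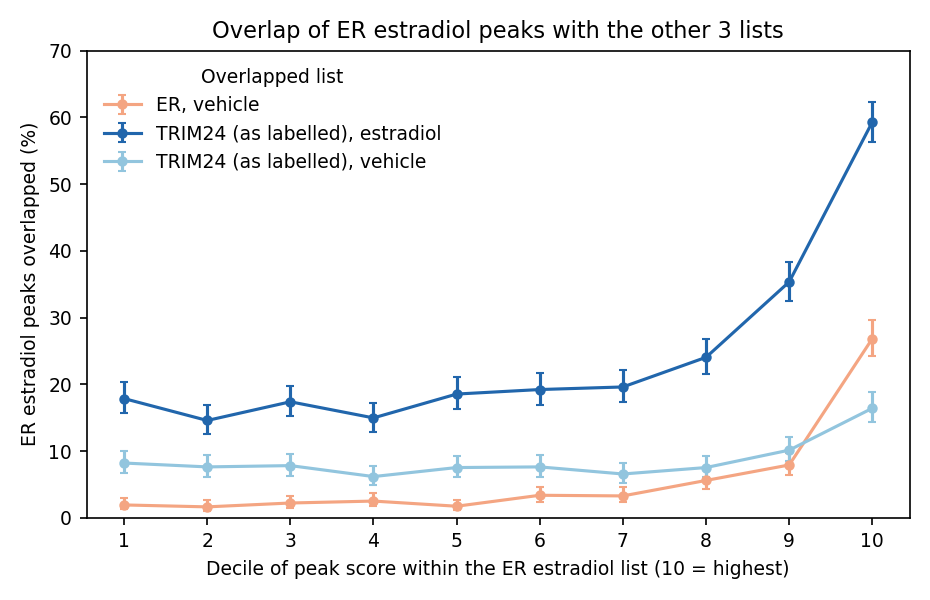
Share of ER estradiol peaks (y axis, percent) that overlap a peak of each of the other 3 lists, by decile of the authors' score within the ER estradiol list (x axis, 10 highest). Points are shares and bars are 95% Wilson intervals; the share with TRIM24 estradiol peaks reaches 59.3% in decile 10.

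TRIM24 with and without estradiol was also compared at the same ER sites, a comparison added after the data had been examined. At the 10350 ER estradiol peaks, TRIM24 peaks were present at 2494 (24.1%) with estradiol and at 887 (8.57%, 8.05 to 9.12) with vehicle, a ratio of 2.81. The TRIM24 estradiol list is longer, and after local shifts the means were 1.86% and 0.936%, a ratio of 1.99. There was a TRIM24 peak only with estradiol at 1875 of these sites, only with vehicle at 268, under both conditions at 619 and under neither at 7588. At the 1035 ER peaks of the top score decile the shares were 59.3% with estradiol and 16.4% (14.3 to 18.8) with vehicle, a ratio of 3.61. Sites where both ER and TRIM24 peaks were found only with estradiol numbered 1666 ER peaks. They were led by the region on chromosome 20 from 52173311 to 52174130, another on chromosome 20 from 58071049 to 58072129 (2717), chromosome 14 from 103229083 to 103230071 (2258) and chromosome 1 from 7430317 to 7431071 (2169).

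With the TRIM24 estradiol list shortened by score to the 7872 peaks of the vehicle list, 1858 ER sites (17.95%, 17.2 to 18.7) had a TRIM24 estradiol peak and the ratio was 2.09, against 1.17 after local shifts. The same lists at the 6392 ER vehicle peaks gave 10.2% with the full and 7.60% with the shortened estradiol list and 4.76% with the vehicle list, ratios of 2.15 and 1.60 against 1.82 and 1.06 after local shifts. The vehicle share of 8.57% was 5.08% when an overlap of at least 50% of both peaks was asked for, and the estradiol share was then 16.6%. With gaps of up to 1 kb the shares were 12% with vehicle and 28.9% with estradiol.

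**Figure D4:**
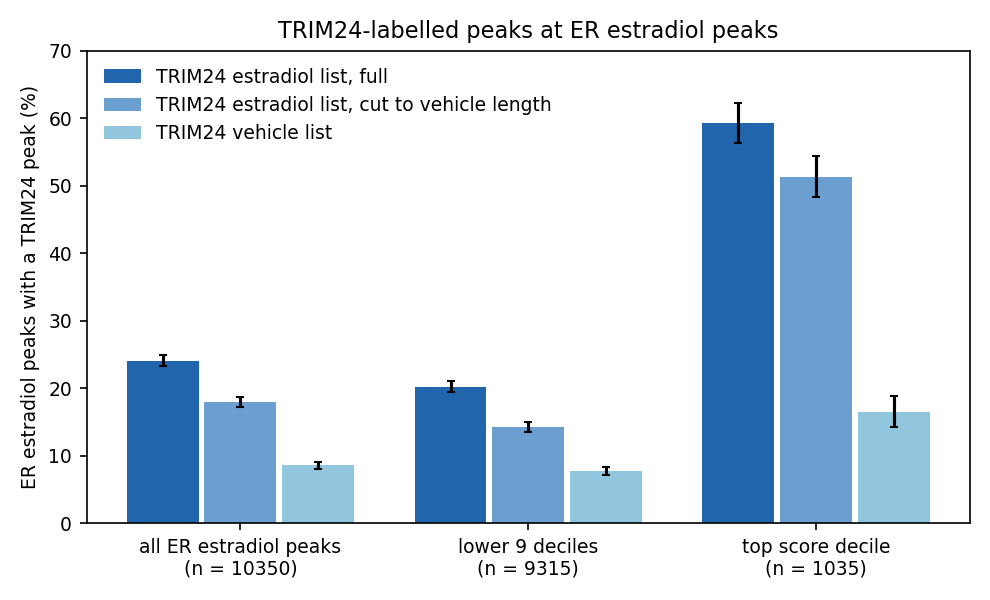
Share of ER estradiol peaks with a TRIM24 peak (y axis, percent) for all 10350 peaks, the lower 9 deciles of score and the top decile. Bars show the full TRIM24 estradiol list, that list shortened to the length of the vehicle list, and the vehicle list, with 95% Wilson intervals; in the top decile they stand at 59.3, 51.3 and 16.4%.

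The last comparisons asked whether peaks found only with estradiol carried the other protein more often than peaks found under both conditions. They carried it less often. A TRIM24 estradiol peak lay at 2165 of 9759 estradiol-only ER peaks (22.2%) and at 329 of 591 ER peaks found under both conditions (55.7%), a difference of -33.5 percentage points (-37.5 to -29.4). An ER estradiol peak lay at 15.2% of estradiol-only TRIM24 peaks and at 26.1% of TRIM24 peaks found under both conditions, a difference of -10.9 points (-12.8 to -9.09).

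The classes differed in score, with medians of 94.8 for estradiol-only ER peaks and 282 for ER peaks under both conditions. Within quartiles of the ER score the differences in TRIM24 were -23.9, -29.6, -24.1 and -22.0 points from the lowest to the highest quartile, and every interval lay below 0. For ER at TRIM24 peaks the differences were -8.44 and -9.32 points in the lower quartiles of score. In the upper quartiles they were -2.12 (-5.73 to 1.07) and -2.79 points (-6.12 to 0.484), and both intervals included 0. Within quartiles of width the differences for ER at TRIM24 peaks were -8.48, -10.4, -6.12 and -6.19 points from the lowest quartile. For TRIM24 at ER peaks they were -26.1, -21.0, -18.2 and -29.3 points. All of these intervals for quartiles of width lay below 0. The difference for TRIM24 was -22.2 points without sites common to all lists. That step takes out shared ER peaks that meet TRIM24, so it shrinks the difference by construction. With lists of equal length the difference for ER was -4.41 points.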

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

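The alternatives were set before the data were examined, except leaving out peaks that overlap all 3 other lists and the result on TRIM24 vehicle peaks at ER estradiol peaks, which were added later. Of 72 values under 8 alternatives for 9 results, 27 lay within the interval of the value reported and 45 lay outside it. Both differences between classes stayed negative under every alternative. The other results are shares, which cannot change sign. Causes were not tested where the construction of an alternative does not show them; a stricter overlap lowers sharing and a wider gap raises it by construction. With an overlap of at least 50% of both peaks, the share found only with estradiol was 95.9% for ER and 89.4% for TRIM24, and the share found only with vehicle 93.4% and 80.5%. ER peaks then met TRIM24 at 16.6% with estradiol and 2.68% with vehicle, and the difference in ER at TRIM24 peaks was -8.25 points. With centres within 500 bp, TRIM24 peaks found under 1 condition were 84.5% with estradiol and 71.4% with vehicle, and 23.04% of ER estradiol peaks met TRIM24. With gaps of up to 1 kb, peaks found only with estradiol were 92.3% for ER and 78.4% for TRIM24, those only with vehicle 88.6% and 62.2%, and ER met TRIM24 at 28.9% with estradiol and 7.17% with vehicle. In the higher scored 50% of each list, the shares only with estradiol were 93.8% and 84.1%, those only with vehicle 89.9% and 70.5%, ER with TRIM24 in vehicle 3.97%, and the difference in ER at TRIM24 peaks -4.51 points. With 6392 peaks from each list, the shares only with estradiol were 92.02% and 77.8%, those only with vehicle 92.02% and 77.1%, ER with TRIM24 20.5% and 4.22%, and the difference in ER at TRIM24 peaks -4.41 points. Without chromosomes 1, 17 and 20, TRIM24 peaks found only with estradiol were 83.9% and ER estradiol peaks with TRIM24 23.04%. Merging peaks within 500 bp moved no planned result outside its interval. Without peaks that overlap all 3 other lists, which removes shared peaks by construction, the shares only with estradiol were 95.4% and 84.0%, those only with vehicle 92.5% and 70.1%, ER with TRIM24 23.04% and 2.98%, and the differences -22.2 points for TRIM24 at ER peaks and -6.88 for ER at TRIM24 peaks. Over all 8 alternatives these differences ranged from -34.2 to -22.2 and from -11.7 to -4.41 points. No paired analysis was possible because each group held 1 sample. Alternatives for promoter shares, motif shares and gene lists were not run, since no genome or annotation of the build was used here. Depth per library is unknown, so its effect on which peaks pass the threshold could not be measured.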

Other observations

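All tests and counts in this part were chosen after the results had been seen. The densest 1 Mb bins of the proteins were partly shared, and no test of the difference was run. The bin on chromosome 20 from 48000001 to 49000000 ranked 1 for ER and 3 for TRIM24 with estradiol, and that from 45000001 to 46000000 ranked 4 and 5. TRIM24 estradiol peaks were most numerous on chromosome 16 from 87000001 to 88000000, with 78 peaks against 24 ER estradiol peaks, and on chromosome 20 from 61000001 to 62000000, with 64 against 12. ER estradiol peaks were most numerous on chromosome 20 from 48000001 to 49000000, with 44 peaks, and from 46000001 to 47000000, with 38, where TRIM24 had 59 and 40. The bin on chromosome 17 from 52000001 to 53000000 held more ER than TRIM24 estradiol peaks, 28 against 14. ER vehicle peaks were most numerous on chromosome 17 from 57000001 to 58000000, with 19 peaks against 11 with estradiol.

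Of the 1000 highest scored TRIM24 estradiol peaks, 539 met an ER estradiol peak and 510 a TRIM24 vehicle peak. The 510 included 261 without an ER estradiol peak, another 290 met an ER estradiol peak without a TRIM24 vehicle peak, and 200 met neither. Sites common to all 4 lists numbered 136, with 16 on chromosome 17, 13 on chromosome 16, 11 on chromosome 20 and 3 on chromosome Y. Chromosome Y held 5 ER estradiol, 9 ER vehicle, 13 TRIM24 estradiol and 12 TRIM24 vehicle peaks. Whether these are background common to the libraries was not tested.

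ER vehicle peaks were mostly missing from the ER estradiol list, and 94.9% of the 5802 vehicle-only peaks scored under 100. If they were calls at chance positions as a whole, they would meet TRIM24 peaks no more often than their own neighbourhoods do. A peak in either TRIM24 list lay at 7.01% of them (407 peaks), against a mean of 1.63% and a maximum of 2.10% over 1000 local shifts, which argues against chance positions as the whole cause. Most vehicle-only peaks met no peak of either TRIM24 list, and chance calls may still make up part of them. Background common to the libraries and ER binding without hormone stay open.

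Very wide TRIM24 peaks crowded on chromosomes 17 and 20: of 31 TRIM24 estradiol peaks wider than 3 kb, 28 were there, and 21 lay in 4 bins of 1 Mb, from 56 to 57 Mb on chromosome 17 and from 45, 51 and 55 Mb on chromosome 20. Of these 21, 14 (66.7%, 45.4 to 82.8) met a TRIM24 vehicle peak. Over 1000 placements of the same peaks within their own bins the mean was 20.4% and the maximum 47.6%. Placement was even over each bin, but both TRIM24 lists crowded in part of the chromosome 20 bin from 55 Mb. The background may thus be too low, so no conclusion on a need for estradiol is drawn. Extra copies of these regions, known in MCF7, would raise the density of every list, and the densities were 6.81, 3.10, 7.87 and 12.96 times the genome mean for ER estradiol, ER vehicle, TRIM24 estradiol and TRIM24 vehicle. Against the rest of chromosomes 17 and 20 they were 3.10, 1.52, 3.11 and 4.60 times, and the bins had been chosen by their TRIM24 estradiol peaks. Extra copies and dense binding of both proteins there cannot be told apart, since no copy number was measured.

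The track lines of the lists labelled TRIM24 contain ER, as do those of the ER lists. If the TRIM24 estradiol list held ER chromatin, most of the strongest ER peaks would be in it, and 84 of the top 100 were (75.6 to 89.9%). A coactivator present at ER sites would give the same value, so the explanations cannot be told apart from these lists. The 461 of the 1000 highest scored TRIM24 estradiol peaks that met no ER estradiol peak may come from TRIM24 binding or from background of the libraries. Reads of an antibody-independent control were not analysed here.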
